A study of Mus musculus with 6 samples.

How the data were processed

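The series compared the cortex of newborn mice (postnatal day 0) that carry 1 disrupted copy of Npas3 (Npas3+/-) with wild-type (WT) cortex. Npas3 encodes a basic helix-loop-helix PAS transcription factor expressed in the nervous system. There were 3 Npas3+/- and 3 WT libraries of total RNA, sequenced in bulk, all labelled with the strain C57BL/6. Each library was assigned to its genotype and replicate number from the labels. The columns of the table carry the abbreviation NP for the libraries that are not WT, and these were taken as Npas3+/-, the only other genotype. The labels do not say that the replicates came from separate animals, so p-values measure only the spread between these samples.

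The authors deposited 1 table of raw read counts per gene, with 53379 genes. Per the submitters' processing notes, Trimmomatic 0.3.8, HISAT2 2.1.0 and featureCounts were used with the mm10 genome. The featureCounts version, the annotation release, the use of strand and the treatment of reads with several matches were not given in the sources used here. Counts of genes that overlap on opposite strands, or that share sequence with copies elsewhere, are therefore uncertain. The gene identifiers were matched without their version to GENCODE release M21 of the same genome build, which gave symbols and coordinates for 53274 of them and left 105 unmatched. Total counts per library ran from 67378231 to 87811574.

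Counts were analysed as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on genotype, which left 21244, and libraries were scaled by TMM. A quasi-likelihood model with genotype as its only term was fitted with glmQLFit and tested with glmQLFTest. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Fold changes are log2 of Npas3+/- over WT, and their standard errors (SE) are the fold change divided by the square root of the F statistic. Levels are CPM, scaled for depth by edgeR, as mean ± SD. With 3 libraries against 3, an exact two-sided permutation test cannot give a p below 0.1, so no such test was used for a single value. The biological coefficient of variation was 26.1%.

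A total of 40 gene lists were fixed before the data were examined. They covered cell types of the cortex (astrocyte, radial glia, intermediate progenitor, upper-layer and deep-layer projection neuron, interneuron, oligodendrocyte lineage, microglia, endothelium, pericyte, meninges, red blood cell, choroid plexus) and neighbouring regions (ganglionic eminence and striatum, hippocampus, thalamus, olfactory bulb). The others covered cell cycle, synapses, ion channels, signalling pathways, bHLH-PAS relatives, metabolism, ribosome, stress, histones, autism risk genes, axon guidance and maturing neurons. A list of Xist, Tsix and Y-linked genes was read per library and not tested. The other 39 lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, which asks whether a list moved relative to the other genes. Camera with an estimated correlation and fry, which asks whether the members of a list moved on balance in 1 direction, were run beside it. A list score is the mean over members of the deviation of log2 CPM (prior count 2) from the mean of the 6 libraries.

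The genes named were set by a rule written before the data were examined. It took Npas3, the 10 largest changes in each direction past the threshold with a mean of at least 1 CPM and no overlap between groups, the 5 smallest p-values in each direction at a mean of at least 10 CPM, and the 4 members with the smallest p in each list. Some genes that the rule took are not reported here. Where fewer than 5 genes passed in a direction, the 5 with the smallest p at a mean of at least 1 CPM were added.

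Alternatives set before the data were examined were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, other low-count filters, the replicate number as a block, mitochondrial and haemoglobin genes left out, a covariate of Y-linked expression, other thresholds, and each library left out in turn. Alternatives chosen after seeing the data were a correction for GC content of the transcripts (a lowess with span 0.4 per library, entered as offsets), that correction together with the block, the striatal list score as a covariate, and robust empirical Bayes moderation. Shared sequence was measured as 50-base windows of the annotated transcripts that also lay in transcripts of genes elsewhere. For each called gene the change in CPM was set against the summed change of the genes sharing its windows, a test chosen after seeing the data.

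The steps were tested on simulated counts for the 21244 genes with the means, dispersions and depths of these libraries, with 200 genes changed. For this comparison edgeR called 25.4% of the genes changed 1.5-fold, 61.2% of those changed 2-fold and 87.9% of those changed 4-fold. Among the unchanged genes it made 4 calls, and DESeq2 made 43. Camera found a list lowered by 0.3 on the log2 scale (adjusted p = 1.31e-07), and called 0 of 39 lists in counts with no change. The simulation matched means, dispersions and depths, and not the correlation between genes of a list. Among the lists called in the data, that correlation was estimated at -0.075 (olfactory bulb) to 0.591 (ganglionic eminence and striatum). Other splits of the libraries, which mix the genotypes, called up to 8 lists. The simulation therefore does not give the rate of false list calls in these libraries. A simulated trend of fold change on GC had a slope of 2.04 before the correction and 0.034 after it.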

Results

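Gene expression was measured by RNA sequencing in cortex taken at postnatal day 0 from 3 Npas3+/- and 3 WT samples. Total counts were 87811574, 78016229 and 75540885 in Npas3+/- replicates 1 to 3 and 67378231, 83256308 and 71862864 in the WT replicates. Log2 CPM of libraries of the same genotype correlated with a mean Pearson r of 0.972 across genes, and pairs from different genotypes ranged from 0.965 to 0.975. The closest pair within a genotype had a chi-square of 42.2 per gene between its counts, so no library repeated another. On the leading principal component, which held 28% of the variance, Npas3+/- replicates 1 and 2 lay at -65.9 and -44.1. Npas3+/- replicate 3 lay at 23.1, among the WT libraries at 28.4, 47.7 and 10.8. Xist was at 3667 CPM in Npas3+/- replicate 2 and at 2.03 CPM or less in the other 5 libraries.

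The comparison of genotypes asked how the loss of 1 copy of Npas3 changes the newborn cortical transcriptome. Npas3 itself (ENSMUSG00000021010, mm10 chromosome 12, 53248677 to 54072175) stood at 12.6 ± 3.45 CPM in Npas3+/- cortex and 25.9 ± 2.53 CPM in WT (SD, n = 3), 48.6% of the WT level. Its counts were 1315, 1087 and 650 in the Npas3+/- libraries and 1583, 2388 and 1845 in WT, so all 3 Npas3+/- values lay below all 3 WT values. The log2 fold change was -1.04 (SE 0.21) and did not pass over all genes in edgeR's quasi-likelihood test (adjusted p = 0.27). DESeq2 placed it past the threshold, at -1.04 with an adjusted p of 7.84e-05. Npas3+/- replicate 3 had the lowest level, 8.61 CPM, against 14.96 and 14.13 CPM in replicates 1 and 2.

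Of 21244 genes tested, 8 passed the threshold in edgeR, 6 higher and 2 lower in Npas3+/- cortex, and in each of the 8 the groups did not overlap. The largest change was in Zbtb9, a BTB-domain zinc finger gene on chromosome 17 (26973167 to 27008376), which rose from 0.651 ± 0.070 CPM in WT to 25.1 ± 0.971 CPM in Npas3+/- (SD, n = 3). Its log2 fold change was 5.27 (SE 0.13, adjusted p = 1.11e-05), with 41 to 59 counts per WT library and 1866 to 2194 per Npas3+/- library. Ggnbp1, which codes for a gametogenetin-binding protein and starts 9.61 kb beyond the end of Zbtb9, fell in the same libraries from 31.8 ± 2.58 to 8.60 ± 1.80 CPM (log2 fold change -1.89, SE 0.16, adjusted p = 0.0142). Tmem127 on chromosome 2 (127247908 to 127261107), an endosomal membrane protein known as a negative regulator of mTOR signalling, rose from 21.4 ± 1.34 to 138 ± 7.87 CPM (log2 fold change 2.69, SE 0.08, adjusted p = 1.4e-05).

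Sybu, which encodes syntabulin, a linker of kinesin to axonal cargo, rose from 143 ± 8.98 to 320 ± 25.8 CPM (log2 fold change 1.16, adjusted p = 0.00297). The zinc finger gene Zfp316 rose by 0.80 (adjusted p = 0.0142) and Krcc1, which codes for a lysine-rich coiled-coil protein, by 1.59 (adjusted p = 0.0412), both on the log2 scale. Slc4a4, the electrogenic sodium bicarbonate cotransporter found in astrocytes, fell from 39.7 ± 5.83 to 14.7 ± 1.79 CPM (log2 fold change -1.44, SE 0.14, adjusted p = 0.03). Sybu, Krcc1, Ggnbp1, Rpl30 and Npas3 itself each overlap a gene on the opposite strand, and the counting may not have separated them. In edgeR, the call of Krcc1 was lost with any 1 library left out (adjusted p 0.0752 to 0.195), as were those of Slc4a4 (up to 0.14) and Zfp316 (up to 0.114) in 5 of these 6 fits each, and that of Ggnbp1 without replicate 3 of either genotype (up to 0.0668). Zbtb9, Tmem127, Rpl30 and Sybu passed in all 6.

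**Figure D1:**
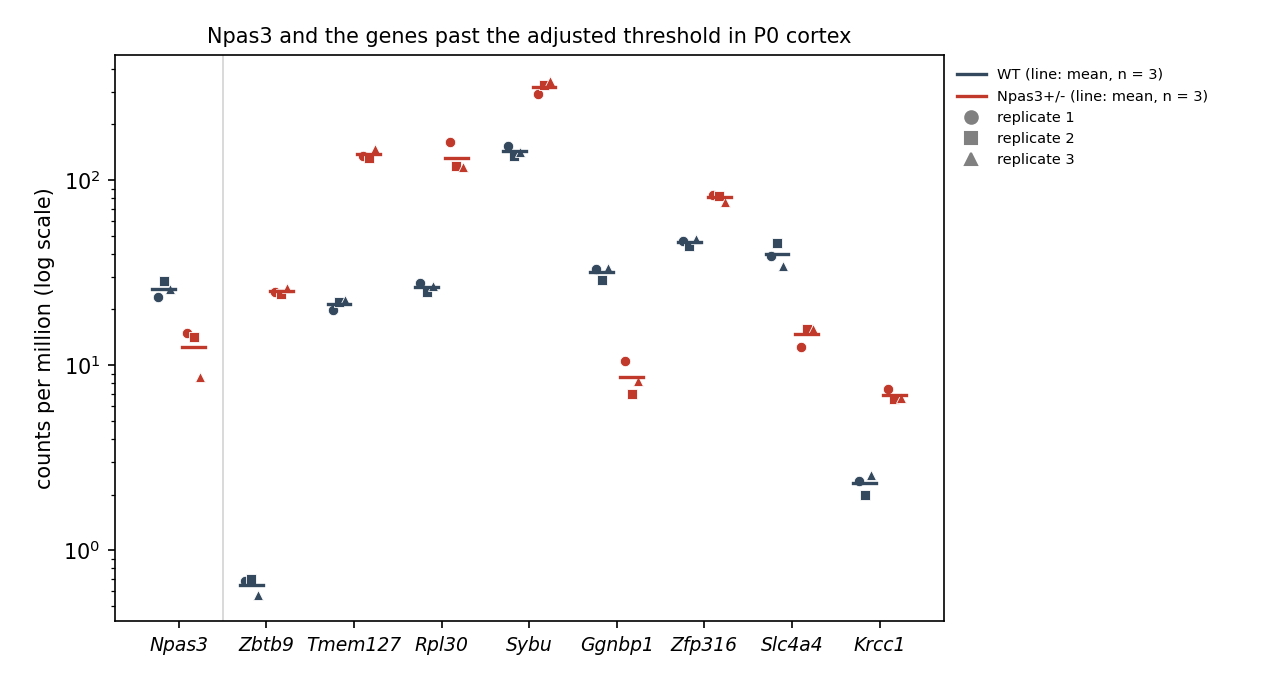
CPM (log axis) of Npas3 and the 8 genes past the threshold in each of the 3 WT (dark) and 3 Npas3+/- (red) libraries of postnatal day 0 cortex. Marker shapes give the replicate and lines the group means. Zbtb9 lies at 0.571 to 0.703 CPM in WT and 24.3 to 26.2 CPM in Npas3+/-, and the groups do not overlap for any gene shown.

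The ribosomal protein gene Rpl30 (chromosome 15, 34440505 to 34443640) was counted at 26.5 ± 1.44 CPM in WT and 133 ± 23.7 CPM in Npas3+/- (log2 fold change 2.32, SE 0.13, adjusted p = 0.00126). Its processed pseudogene Gm12191 on chromosome 11 went the other way, from 180 ± 13.8 to 98.3 ± 13.2 CPM (log2 fold change -0.87, adjusted p = 0.0861), and Rpl30-ps9 stood at 17.6 ± 1.51 CPM in WT and 8.91 ± 1.82 CPM in Npas3+/-. All 299 windows of 50 bases in Gm12191 also occur in transcripts of other genes, so reads of the family cannot be assigned with certainty. Summed over Rpl30 and its 14 copies, the family stood at 245 ± 13.7 CPM in WT and 258 ± 20.0 CPM in Npas3+/-, a log2 difference of 0.07, less than the SD of 0.12 among the Npas3+/- libraries.

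**Figure D2:**
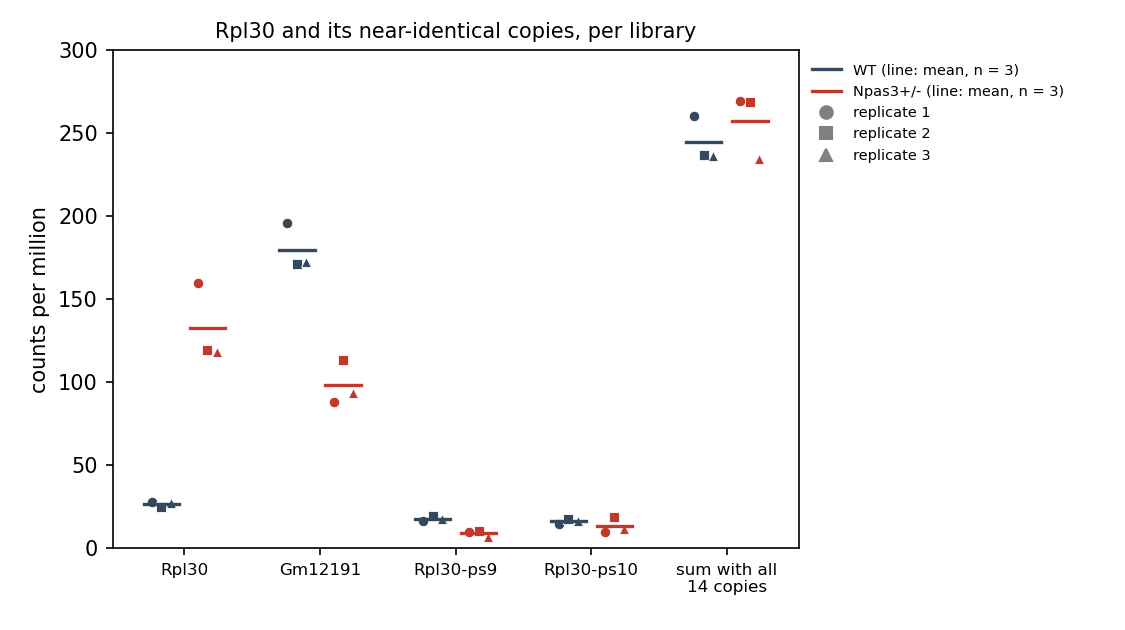
CPM (linear axis) of Rpl30, 3 of its copies and the sum of Rpl30 with all 14 copies in each WT (dark) and Npas3+/- (red) library. Lines are means of 3. Rpl30 lies at 24.9 to 27.7 CPM in WT and 118 to 160 CPM in Npas3+/-, Gm12191 is lower in Npas3+/-, and the sums overlap.

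Among genes that did not pass in edgeR, those with the smallest p in the lower direction were Gm12191, the microtubule-severing gene Fign (log2 fold change -2.29, SE 0.31, adjusted p = 0.155), the intermediate filament gene Vim (-0.79, SE 0.11, adjusted p = 0.17) and the unclassified transcript Gm43300 (-0.74, SE 0.11, adjusted p = 0.231). DESeq2 called each of these genes (adjusted p = 3.38e-11, 8.47e-10, 2.19e-08 and 1.37e-06). At an unadjusted p under 0.05 there were 2576 genes, 1336 higher and 1240 lower, where chance would give 1062 on average. Genes that vary together widen the spread around that average. Other splits of the 6 libraries into 3 and 3 gave 430 to 1402 such genes. With the striatal list score as a covariate the genotypes gave 1193. The groups did not overlap for 18.9% of genes, where chance gives 10%. DESeq2 called 425 genes, 222 higher and 203 lower. All 425 had the same direction in edgeR, which adds no support since both methods fit the same counts. Their median absolute log2 fold change was 0.47. In other splits of the libraries DESeq2 called at most 172 genes.

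Markers of radial glia and astrocytes were lower in Npas3+/- cortex. Of the 26 radial glia and ventricular zone genes, 22 had negative log2 fold changes and the median was -0.26. Vim stood at 63.0 ± 7.42 CPM against 109 ± 11.7 in WT, and Fabp7, the brain lipid-binding protein, at 298 ± 32.8 against 431 ± 25.4 CPM (log2 fold change -0.53, SE 0.09). Ptprz1, a receptor tyrosine phosphatase (-0.28), and Notch3 (-0.40) were the other members past the threshold adjusted over the list alone, where 4 passed; over all genes 0 passed. Of the 28 astrocyte genes tested, 24 were lower with a median of -0.26. Slc1a2, the main glial glutamate transporter (-0.45, SE 0.10), and Fabp7 passed adjusted over the list alone, with 0 over all genes in edgeR. DESeq2 called Slc1a2 (adjusted p = 0.0136) and Fabp7 (5.47e-05) over all genes. Both lists passed camera with the preset correlation (adjusted p = 3.49e-08 for radial glia and 3.56e-07 for astrocytes) and neither did otherwise (adjusted p = 0.671 with an estimated correlation and 0.327 by fry). The lists share 4 members. The astrocyte score was -0.22 and -0.31 in Npas3+/- replicates 1 and 2 but 0.09 in replicate 3, above the 0.02 of WT replicate 3. Without Npas3+/- replicate 3 the medians were -0.42 for radial glia and -0.40 for astrocytes.

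Most members of the interneuron, striatum, olfactory bulb and inhibitory synapse lists were also lower. In the interneuron list, whose genes need not be confined to interneurons, 25 of 28 were lower, with a median log2 fold change of -0.29. Gad2, a GABA-synthesizing enzyme, stood at 58.7 ± 17.7 CPM against 104 ± 17.0 in WT (-0.82, SE 0.21), the somatostatin gene Sst at 27.3 ± 6.31 against 46.0 ± 18.1 CPM, and Reln, which encodes the extracellular protein reelin, at 217 ± 16.3 against 302 ± 50.7 CPM. In the ganglionic eminence and striatum list 18 of 21 genes were lower with a median of -1.13, among them Tac1 (-3.00, SE 0.94), Ebf1 (-1.98, SE 0.84) and Adora2a (-1.13, SE 0.48). The olfactory bulb list had 9 of 12 genes lower and a median of -0.70, with Pbx3 at -1.21 (SE 0.35), Cdhr1 at -1.26 (SE 0.48) and Nrsn1 at -0.30 (SE 0.08), and the inhibitory synapse list had 18 of 24 lower and a median of -0.07. In each of these 4 lists 0 genes passed over all genes and 0 adjusted over the list alone. The interneuron and inhibitory synapse lists share 3 members, Gad2 among them, so their results are not independent. Camera with the preset correlation gave adjusted p = 4.7e-06 for interneurons, 4.79e-06 for striatum, 0.00149 for olfactory bulb and 0.0237 for the inhibitory synapse. The calls were lost with an estimated correlation (adjusted p = 0.671, 0.671, 0.671 and 0.714 with an estimated correlation) and by fry (lowest adjusted p = 0.0595, for olfactory bulb).

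The striatal score differed widely within genotypes. It was -1.24, -1.23 and 0.41 in Npas3+/- replicates 1 to 3 and 1.04, 1.45 and -0.42 in WT, so the groups overlapped. With that score as a covariate, an alternative chosen after seeing the data, the interneuron, astrocyte, inhibitory synapse, microglia and upper-layer lists no longer passed (medians -0.07, -0.11, -0.01, -0.07 and 0.03; adjusted p = 0.144, 0.11, 0.942, 0.436 and 0.436). Radial glia (-0.19, adjusted p = 0.00137), olfactory bulb (-0.39, 0.00137), cholesterol synthesis and the mitochondrial list still passed. The log2 fold changes then stood at -0.41 for Gad2, -0.21 for Sst, -0.38 for Pbx3 and -0.56 for Cdhr1. Sst overlapped between the groups, with 34.5 CPM in Npas3+/- replicate 3 against 33.9 CPM in WT replicate 3, and WT replicate 2 stood highest at 66.8 CPM. The olfactory bulb score was below all WT values in all 3 Npas3+/- libraries. The inhibitory synapse list did not pass without Npas3+/- replicate 2 (median -0.12, adjusted p = 0.123), without WT replicate 2 (-0.02, adjusted p = 0.524), with the GC correction (-0.06, adjusted p = 0.079) or with the Y-linked covariate (-0.12, adjusted p = 0.129). Its median was -0.13 without Npas3+/- replicate 1 and -0.14 without WT replicate 3. Without Npas3+/- replicate 3 the medians were -1.92 for striatum and -0.45 for interneurons, and the olfactory bulb median was -0.31 without WT replicate 1 and -0.34 without WT replicate 2. With a filter of 1 CPM in 3 libraries the olfactory bulb median was -0.31 and the list did not pass (adjusted p = 0.0686).

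**Figure D3:**
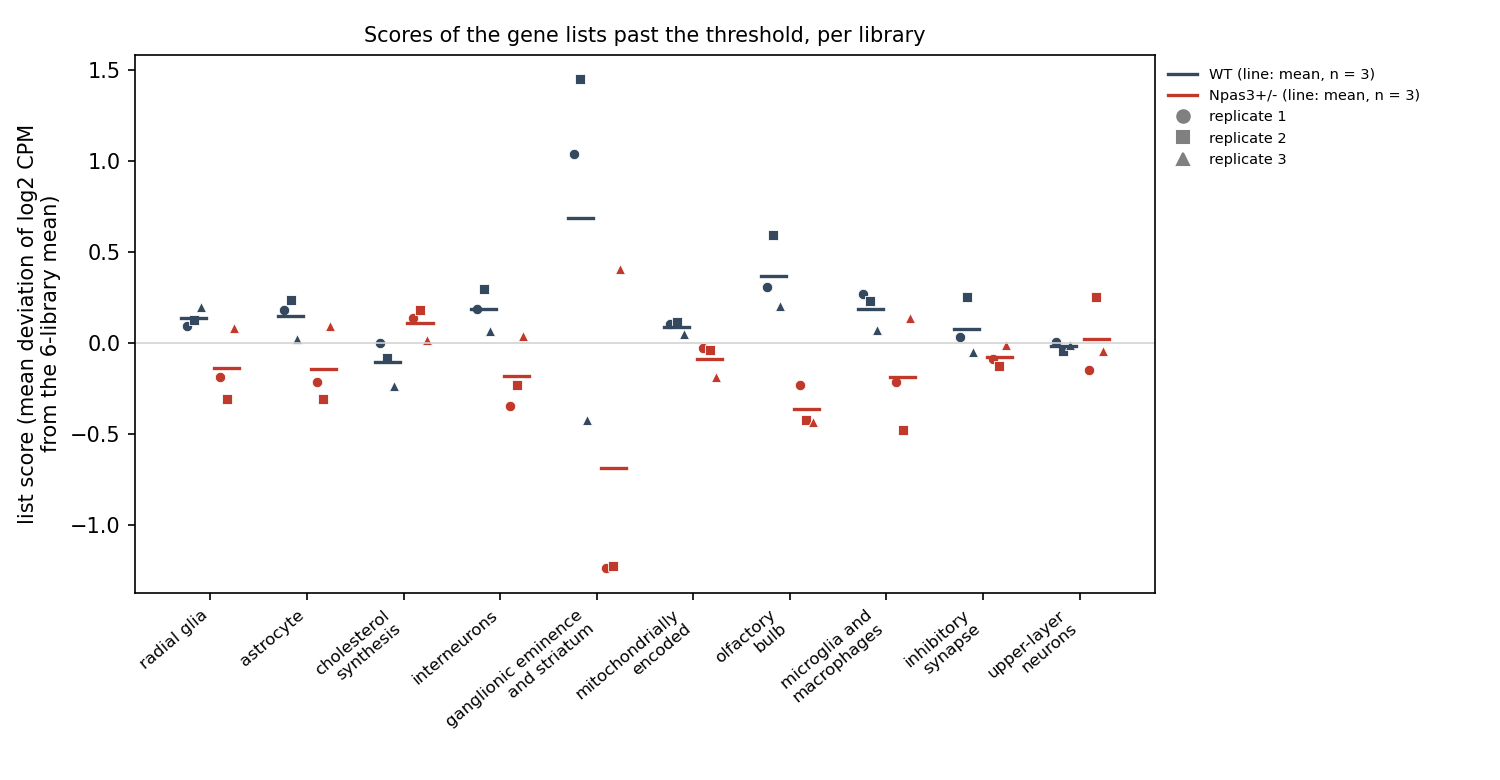
Score of each gene list past the threshold (mean deviation of log2 CPM from the mean of the 6 libraries) in the WT (dark) and Npas3+/- (red) libraries, with group means as lines. Npas3+/- replicate 3 scores 0.41 on the ganglionic eminence and striatum list, against -1.24 and -1.23 in the other Npas3+/- libraries, and WT replicate 3 scores -0.42.

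Genes of cholesterol synthesis were higher in Npas3+/- cortex, 22 of 24 with a median log2 fold change of 0.20. Mvd, the mevalonate diphosphate decarboxylase, stood at 59.9 ± 4.94 CPM against 41.3 ± 7.22 in WT (0.54, SE 0.13), Stard4, a cholesterol transfer protein, at 37.0 ± 5.81 against 25.8 ± 2.56 CPM (0.52, SE 0.13), and Srebf2, the transcription factor that drives the pathway, at 321 ± 5.06 against 279 ± 4.58 CPM (0.20, SE 0.04; 0.11 with the trend of fold change on GC content removed). These 3 passed adjusted over the list alone and 0 over all genes in edgeR. DESeq2 called Mvd (adjusted p = 0.00848) and Stard4 (0.017) over all genes. The list passed camera (adjusted p = 3.56e-07) but not with other settings of the test (adjusted p = 0.671 with an estimated correlation and 0.327 by fry). Upper-layer projection neuron genes mostly had small positive log2 fold changes, 16 of 20 with a median of 0.08 (camera adjusted p = 0.0311, or 0.712 with an estimated correlation). The list score was not higher throughout the Npas3+/- group. It was 0.252 in replicate 2, but -0.151 and -0.045 in replicates 1 and 3, below the WT values of 0.002, -0.044 and -0.014. Pou3f1 (0.48, SE 0.11), Rasgrf2 (0.55, SE 0.12) and Dok5 (0.37, SE 0.10) passed adjusted over the list alone and 0 genes over all genes in edgeR. DESeq2 called these 3 over all genes (adjusted p = 0.00659, 0.00545 and 0.04). The camera call of the upper-layer list was lost without Npas3+/- replicate 2 (median 0.04, adjusted p = 0.838) and without WT replicate 2 (0.01, adjusted p = 0.211). Its median was 0.19 without Npas3+/- replicate 1, 0.14 without WT replicate 1 and 0.13 without WT replicate 3. The list call was also lost with limma-voom (adjusted p = 0.0613), the filter of 1 CPM (0.0623), the Y-linked covariate (0.935) and the striatal covariate (0.436), with which Pou3f1 stood at 0.26 and Dok5 at 0.21.

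All 13 mitochondrially encoded genes were lower in Npas3+/- cortex, with a median of -0.14. The complex I genes mt-Nd1 (-0.24), mt-Nd2 (-0.28), mt-Nd4l (-0.15), mt-Nd5 (-0.27) and mt-Nd6 (-0.32) passed adjusted over the list alone and 0 over all genes in edgeR. DESeq2 called mt-Nd2 (adjusted p = 0.0141), mt-Nd5 (0.0339) and mt-Nd6 (0.0207) over all genes. The list passed camera with the preset correlation (adjusted p = 3.87e-05) and not with an estimated correlation (adjusted p = 0.671). Fold changes followed the GC content of transcripts, from a median of -0.08 in the fifth of genes with the lowest GC to 0.07 in that with the highest. With this trend removed, an alternative chosen after seeing the data, the mitochondrial list had a median of -0.04 and did not pass (adjusted p = 0.0791); without Npas3+/- replicate 3 the median was -0.09. Microglia and macrophage genes were lower, 22 of 25 with a median of -0.32, among them Mrc1 (-0.90, SE 0.29) and Ptprc (-1.01, SE 0.30), with 0 past the threshold over all genes and 0 adjusted over the list alone (camera adjusted p = 0.00149; adjusted p = 0.671 with an estimated correlation). Without Npas3+/- replicate 2, the library with Xist, the microglial median was -0.10 and the list did not pass (adjusted p = 0.138); without Npas3+/- replicate 3 it was -0.51. With the striatal score as a covariate it was -0.07 (adjusted p = 0.436), and Mrc1 stood at -0.53.

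In all, 10 of 39 lists passed camera with the preset correlation, 8 lower and 2 higher; with an estimated correlation 0 passed and 1 was at an unadjusted p under 0.05, and by fry 0 passed and 3 were. Dividing and committed progenitors did not stand apart: the cell cycle list had a median of -0.04 (camera adjusted p = 0.451), and intermediate progenitors 0.05 (0.451). Deep-layer neurons (median 0.01, adjusted p = 0.624), maturing neurons (0.02, 0.636), the oligodendrocyte lineage (0.07, 0.451), the excitatory synapse (-0.03, 0.451) and ion channels (-0.03, 0.925) did not pass. Nor did endothelium (median -0.06, adjusted p = 0.368), pericytes (-0.005, 0.938), meninges (0.03, 0.353), red blood cells (0.02, 0.779), choroid plexus (-0.32, 0.461), hippocampus (-0.08, 0.451) or thalamus (-0.29, 0.15). Among pathways, the values were -0.05 and 0.482 for Notch, 0.04 and 0.461 for Wnt, -0.05 and 0.589 for FGF and sonic hedgehog, -0.08 and 0.61 for BMP and JAK-STAT, and -0.06 and 0.13 for axon guidance. The bHLH-PAS relatives of Npas3 had a median of 0.02 (adjusted p = 0.451), the circadian clock 0.07 (0.205), immediate early genes -0.06 (0.461) and interferon genes -0.23 (0.0758). The medians were 0.02 for glycolysis (adjusted p = 0.734), -0.04 for nuclear-encoded oxidative phosphorylation (0.353), -0.03 for ribosomal proteins (0.589), -0.02 for stress genes (0.671), -0.09 for histones (0.589) and 0 for autism risk genes (0.846). The direction of the camera test was opposite to that of the median for the ribosomal protein, deep-layer, ion channel and red blood cell lists, and the mean was opposite to the median for those but ion channels, and for the oligodendrocyte and histone lists.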

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

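The list of X-inactivation and Y-linked genes was read per library and entered no comparison. It singled out Npas3+/- replicate 2, where Xist, the RNA that coats the inactive X chromosome, stood at 3667 CPM (281988 counts), against 0.153 to 2.03 CPM in the other 5 libraries. Eif2s3y had 24 counts in that library (0.312 CPM) and 91.4 to 106 CPM in the others. The labels give no sex, so sex and genotype are partly confounded, with 1 such library in the Npas3+/- group and 0 in WT. Without this library edgeR called 7 genes, and 5 of the 8 called with all libraries were among them; with Y-linked expression as a covariate it called 7, again with 5 of the 8. In both cases Krcc1, Zfp316 and Slc4a4 were the calls lost, and 7 lists passed camera. Their log2 fold changes stayed at 1.62, 0.79 and -1.49 without this library, and the same 3 calls were lost without Npas3+/- replicate 1, WT replicate 1 or WT replicate 2, so the losses do not point to sex. The sex of the animals stays open as a source of part of the difference in the microglial list, whose median was -0.32 with all libraries and -0.10 without this one; with the striatal covariate it was -0.07.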

How the results depend on the processing

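The GC correction, the striatal covariate, robust moderation and the GC correction with the block were chosen after seeing the data; the other alternatives were planned. The 8 genes called by edgeR remained called with RLE and upper-quartile scaling, limma-voom, a filter of 1 CPM in 3 libraries, mitochondrial and haemoglobin genes left out, the GC correction and robust moderation (8 to 11 calls); Krcc1 was lost without a low-count filter (7 calls). GC content was examined as a source of the 8 calls and of the higher cholesterol list too: with the correction 8 of 8 were kept, and the cholesterol median was 0.17 with the list still past the threshold (adjusted p = 2.26e-07). DESeq2 called 425 genes, 222 higher and 203 lower, including the 8, and gave Npas3 a log2 fold change of -1.04; among the other splits of the libraries it called at most 172. At an adjusted p under 0.01 there were 4 calls, with 0 lower. With the striatal covariate 6 genes were called and 4 of the 8 kept, without Krcc1, Zfp316, Slc4a4 and Ggnbp1, whose log2 fold changes stayed at 1.45, 0.71, -1.23 and -1.99; 1 gene was lower, 4 lists passed, and Adora2a (0.11) changed sign, which says nothing more since it is a member of the list that gives the score. Leaving out 1 library gave 7 to 16 calls (16 without WT replicate 1), with 5 to 11 higher and 2 to 5 lower, and 5 of the 8 kept each time; 7 to 12 lists passed. With a filter of 1 CPM in 3 libraries 8 lists passed, without the olfactory bulb and upper-layer lists. With 1 library left out the Npas3 log2 fold change ran from -1.18 to -0.82 and did not pass. With an estimated correlation 0 lists passed, and by fry 0. The mean correlation of libraries of the same genotype was 0.337 over the 500 most variable genes. The cause of these changes was not tested.

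The genotypes share replicate numbers, but deviations of same-numbered libraries from their group means correlated at 0.04, -0.03 and -0.09, so the numbers were not taken as pairs, and the libraries did not each correlate best with their own number. With the replicate number as a block edgeR called 3 genes, 3 higher and 0 lower (Zbtb9, Tmem127 and Rpl30), and 8 lists passed, without the upper-layer and inhibitory synapse lists. With the block and the GC correction it called 3 genes, 3 higher and 0 lower, and 7 lists passed.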

Other observations

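The splits of the libraries were planned. The tests of Rpl30 and of reads shared by the other 7 genes (which replaced a test by share of windows that Rpl30 itself would have passed, could not tell for the 7 together and was then run in parts), of genetic background, of DNA beside Npas3 and the description of chromosome 12 genes were chosen only after the results they bear on were seen; the striatal covariate and the GC correction were added after seeing the data, with their predictions written before their values were seen.

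The axon guidance list did not pass camera (adjusted p = 0.13), but 7 of its 41 genes passed adjusted over the list alone, 4 higher and 3 lower, with 0 over all genes in edgeR. The ephrin receptor genes Epha3 (log2 fold change -0.46, SE 0.12), Epha5 (-0.32, SE 0.07) and Epha7 (-0.32, SE 0.08) were lower. The ligand genes Efna3 (0.34, SE 0.07) and Sema7a (0.43, SE 0.12), the plexin gene Plxna1 (0.24, SE 0.05; 0.16 with the GC trend removed) and the adhesion gene L1cam (0.18, SE 0.05) were higher. DESeq2 called 6 members, Efna3 (adjusted p = 0.0211), Plxna1 (0.0354) and Sema7a higher and Epha3 (0.0178), Epha5 (0.0188) and Slit2 lower. Boc, a sonic hedgehog coreceptor, was the 1 member of the FGF and sonic hedgehog list past the threshold adjusted over the list alone (0.74, SE 0.14; DESeq2 adjusted p = 2.43e-04), and Fgf9 stood at -0.62 (SE 0.15).

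The excitatory synapse list did not pass (15 members higher and 18 lower). Among its members Grm2 stood at 68.5 ± 9.09 CPM against 41.7 ± 7.69 in WT (log2 fold change 0.72, SE 0.15), while Gria1 (-0.37, SE 0.10) and Grm5 (-0.47, SE 0.14; -0.17 with the striatal covariate) were lower. None passed over all genes in edgeR (adjusted p 0.27 to 0.287), and DESeq2 called all 3 (adjusted p = 5.05e-04, 0.0432 and 0.0311). The oligodendrocyte transcription factor genes Olig1 (0.21, SE 0.06) and Olig2 (0.37, SE 0.10) were higher in 3 of 3 Npas3+/- libraries, with an adjusted p of 0.276 each in edgeR. DESeq2 called Olig2 (adjusted p = 0.0377) and not Olig1 (0.117). With the GC trend removed Olig2 stood at 0.27 and Olig1 at 0.09.

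A run of 20 genes on chromosome 12, from 17.9 to 25.1 Mb and 28.1 Mb before the start of Npas3, parted the libraries across genotypes, 15 with fewer counts and 5 with more in the same 3 libraries. It came from the split that set Npas3+/- replicates 1 and 3 with WT replicate 1, in which 60 pairs among the 100 genes with the smallest p lay within 1 Mb of each other. Gm40847 had 167, 141 and 125 counts in Npas3+/- replicate 2 and WT replicates 2 and 3 and 0 in each of the other 3 libraries, and Gm9259 had 63, 60 and 65 against 0. The ribosomal protein gene Rps2 on chromosome 17 followed the same libraries, at 302, 324 and 324 CPM in the former and 411, 457 and 457 CPM in the latter, and its copy Rps2-ps13 went the other way, at 39.4, 38.5 and 40.4 against 21.5, 21.6 and 22.2 CPM. These genes were chosen after their values were seen.

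For the 8 called genes, 2 of the 10 splits of the 6 libraries called at least 8 genes, the labelled one and 1 other with 15. The split with 15 set Npas3+/- replicates 1 and 3 with WT replicate 1, and is the one that held the chromosome 12 run. The remaining splits called 0 to 5 genes. A set of 10 splits is too small for a share under 0.05. Reads shared with copies may account for Rpl30, since the family sum differed by 0.0732 on the log2 scale. The genes that share its windows moved the opposite way by 0.877 of its own change in CPM. Why the reads were divided differently in the Npas3+/- and WT libraries was not tested, and sharing alone does not give the reason. Shared reads are argued against for Tmem127 and Krcc1, with 0 windows in annotated transcripts elsewhere. They are also argued against for Zbtb9, Sybu and Slc4a4, where that share was at most 0.337 with 2 SE added. For Zfp316 and Ggnbp1 that share was -1.62 and -0.343, as the sharing genes moved the same way. With 2 SE added it reached 1.03 and 9.84. Shared reads therefore cannot be told apart from a change in transcript level for Zfp316 and Ggnbp1. Their 49 and 129 sharing genes varied too much between libraries. DNA of a donor strain beside Npas3 is argued against by 0 of the 8 lying within 10 Mb of it (11% of the genes there were at an unadjusted p under 0.05 and 12.1% elsewhere, Fisher's exact p = 0.866). A difference in genetic background between the groups cannot be told apart from an effect of genotype: 13 pairs of the top 100 genes lay within 1 Mb, between the median of 9 and the 95th percentile of 16 in 1000 matched random lists, and the 60 pairs of the other split are consistent with animals that differ in inherited segments, although the labels give 1 strain, C57BL/6, for all 6 libraries. An effect of Npas3 dosage on Zbtb9, Ggnbp1, Tmem127, Sybu, Zfp316, Slc4a4 and Krcc1 stays open as a hypothesis, which littermates genotyped at these loci would test.

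The lower radial glia and astrocyte lists belong to the 10 lists past the threshold, where the highest other split gave 8; only 1 split, the labelled one, gave as many, and 10 splits are too few for a share under 0.05. GC content is argued against by the medians with the trend removed, of which the higher was -0.288. A single outlying library as the source of the lower medians is argued against by the fits with 1 library left out, where the highest was -0.176. Both lists passed camera each time, but only with the preset correlation, and neither passed with an estimated correlation or by fry in all libraries. The radial glia score of Npas3+/- replicate 3 (0.082) was close to that of WT replicate 1 (0.09). More striatal tissue in the WT dissections cannot be told apart from an effect of genotype. With the striatal score as a covariate the astrocyte median moved from -0.26 to -0.111 and the list did not pass camera (adjusted p = 0.11). The radial glia median was then -0.187 and the list passed camera with the preset correlation (adjusted p = 0.00137). The 2 lists share 4 members and were not tested against each other, so a difference between them is not shown. A lower share of glial cells in Npas3+/- cortex remains a hypothesis, which counts of glial cells in sections would test. Their maturation was not tested, and radial glia genes (22 of 26) were lower along with astrocyte genes (24 of 28).

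The lower interneuron and inhibitory synapse lists may come from more striatal tissue in the WT dissections, since the interneuron median moved from -0.29 to -0.0691 with the striatal score as a covariate. Foxp2, Isl1, Ebf1 and other members of the striatal list are also expressed in neurons outside the striatum. Fewer such neurons in Npas3+/- cortex could therefore lower both lists too, and this was not separated from dissection. The striatal median of -1.13 was further from 0 than the interneuron median, and the striatal score overlapped between the genotypes. Npas3+/- replicate 3 had the lowest Npas3 level of the 6 libraries, yet an interneuron score of 0.04, against -0.35 and -0.23 in replicates 1 and 2. That score was still below the WT values of 0.184, 0.297 and 0.066, so the interneuron score did not overlap between the genotypes. In contrast, the striatal score of Npas3+/- replicate 3 (0.407) was above that of WT replicate 3 (-0.423).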
